A study of Homo sapiens with 28 samples.

How the data were processed

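Trophoblasts isolated from human placenta were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) at 2 stages of primary culture. Per the labels, cells harvested at 0 h were cytotrophoblasts (CytT), the mononucleated progenitors, and cells harvested at 18 h had differentiated into syncytiotrophoblast (SynT), the fused hormone-secreting layer. The labels list 28 libraries in 14 groups of 2. Antibodies against RNA polymerase II (Pol II) were used on sonicated chromatin, and antibodies against H3K4me3, H3K9Ac, H3K27Ac and H3K27me3 on chromatin cut with micrococcal nuclease (MNase). H3K4me3, H3K9Ac and H3K27Ac accompany active promoters and enhancers, and H3K27me3 accompanies repressed genes. The 8 input libraries were made from both kinds of chromatin.

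The values used here are those of 8 deposited lists, a higher and a lower list for each of 4 comparisons of SynT with CytT: Pol II, H3K4me3, H3K9Ac and H3K27Ac. H3K27me3 and the inputs were not analysed here. Each list gives a RefSeq identifier, a symbol and 4 values per gene. The fold change is a deposited log ratio of SynT over CytT and was read as log2, and the mean signal is a deposited log2 of CPM (read counts scaled to library size). The p-value and the false discovery rate (FDR) of each gene are the authors' and were taken as deposited. Per the file headers these columns carry the names that edgeR writes, but no source used here names the program, states the base of the logarithm, or says how the 2 libraries per group or the inputs entered the test. Reads had been processed with Bowtie and bedtools on the hg19 human genome, per the submitters' processing notes, which give no versions. No list gives coordinates, and none are printed.

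The lists hold 1797 rows and no value per library, so sequencing depth per library is unknown and no spread between libraries can be given. How far the authors' p-values measure that spread is taken up in the closing section. Where nothing states that the 2 libraries of a group came from separate cultures or donors, their spread may be technical. No p-value was available for genes outside the lists, so a count of members adjusted over the list alone cannot be made.

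RefSeq identifiers were matched to a RefSeq gene table of the GRCh38.p14 assembly, used only for names, gene class and which genes neighbour each other. Of the rows, 1756 matched by identifier, 23 by symbol and 12 by an older symbol, and 6 had no match. The current symbol replaced the deposited one in 163 rows. Where 2 transcripts of a gene were in a list, the larger change was kept. Genes on the Y chromosome and XIST stayed in the counts but are neither named nor drawn.

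The number of genes the authors tested was recovered from the Benjamini-Hochberg relation between p-value and FDR, in which the number tested times p over FDR is a whole rank. It was 22711 in all 4 comparisons, with whole ranks (within a relative difference of 1e-08) in 94.7% of Pol II rows, 94.2% of H3K4me3 rows, 91.4% of H3K9Ac rows and 96.5% of H3K27Ac rows that had a p-value above 0. The other rows share a rank or carry the FDR of a neighbour. The standard error behind each p-value was derived from the fold change and the normal quantile of the p-value, and split into a part that shrinks with the mean signal and a part that does not.

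Direction agreement between 2 comparisons was tested with a two-sided Fisher's exact test over genes in both, with Benjamini-Hochberg adjustment over 6 pairs. Overlap of the higher lists was tested the same way against 20056 protein-coding genes of the reference table, and that of the lower lists, added later, against 22711 genes. Fold changes were correlated across genes with Spearman's rho and Pearson's r, with 100000 permutations. For 20 gene lists fixed before the data were examined, the higher and lower listed members were compared with all other listed genes by a two-sided Fisher's exact test, with adjustment over the lists with at least 5 listed members (11 for Pol II and 9 for H3K27Ac). Odds ratios had 0.5 added to each cell, and their intervals use a normal approximation. An adjusted p below 0.05 is called significant. Members absent from a list may have changed by less than its limits or not at all.

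Genes named in the text were chosen by a rule fixed before the data were examined. It takes the 12 largest changes in each direction for Pol II and H3K27Ac, the 6 largest for H3K4me3 and H3K9Ac, up to 10 genes that were higher in all 4 comparisons or opposite between Pol II and a mark, and up to 4 members of each fixed list. Unnamed loci, open reading frame symbols and hosts of small RNAs were skipped. Other named genes are the remaining members of a list whose count is given, or are said to be chosen after their values were seen. Lists for H3K4me3 and H3K9Ac were planned as counts and their tests were added later. Lists of neutrophil markers, macrophage markers, imprinted genes, Wnt feedback and target genes, TGF-beta and BMP genes, and chemokines were written after the data were seen and are reported in the closing section, apart from 1 macrophage count.

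Alternatives changed 1 choice at a time: a fold change at least 1.5 times the smallest listed, a 2-fold limit, an FDR 10 times smaller, protein-coding genes only, rows in place of genes, deposited symbols, no multigene families, other backgrounds, Pearson's r, 1 direction only, and lists without shared genes. Chosen after seeing the data were an assumed coefficient of variation of 0.1 or 0.4 between libraries, a background of 22711 genes, tests of all 20 lists for enrichment against protein-coding genes in each direction (adjusted over both directions), and leaving out genes with another listed gene within 2 kb. The assumed variation was added to the error behind each p-value for 2 libraries per group, and genes were counted again at an FDR of 0.001. For the histone marks only listed genes could be ranked, so those counts are lower bounds. Scripts were tested on simulated data first. The number of genes tested was recovered in 2 of 2 simulated tables. For Pol II, with 694 genes, a simulated depth-independent variance of 0.04 came back as 0.0397. Over the 697 Pol II genes, 3.6% of random lists of 10 listed members had an unadjusted Fisher p below 0.05. Lists made 95% lower reached that in 0% of draws with 5 listed members and in 93% with 10. The main tests use an adjusted p, so these simulated rates do not describe them and recovery there can only be lower. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.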

Results

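The series followed human trophoblasts from the cytotrophoblast stage (0 h) to syncytiotrophoblast after 18 h of culture, and asked how Pol II binding and histone marks over genes changed with that differentiation. Each antibody had 2 libraries per stage, and sonicated and MNase-cut inputs had 2 each. All fold changes below are SynT over CytT, read as log2, from the authors' own comparisons of 22711 genes. The tables hold no value per library, so no error can be set beside a fold change, and every significance given for a single gene is the authors' FDR. All listed genes had an FDR under 0.001. Listed histone mark changes were 2-fold or larger, whereas the Pol II lists had no such limit and began at a log2 fold change of 0.12 for higher genes and -0.11 for lower ones. List lengths are therefore not comparable between Pol II and the marks. By the ranks of the p-values, 7092 genes for H3K27Ac, 1908 for H3K4me3 and 1172 for H3K9Ac had an FDR no larger than the largest listed, of which 11.6%, 9.01% and 8.96% were listed, against 100% of 697 for Pol II. Counts and shares for the marks hold for that part alone.

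Pol II binding was higher at 18 h over 317 genes and lower over 380. FN1 (NM_001306129), which encodes the matrix protein fibronectin, had the largest one in the authors' deposited table, a log2 fold change of 2.36, or 5.12-fold. LRRC32, which anchors latent TGF-beta at the cell surface, followed at 2.30 and NOG, which encodes the BMP antagonist noggin, at 2.17 in the authors' deposited table. DEPP1 (deposited as C10orf10) stood at 2.05, the ubiquitin-like interferon-induced gene ISG15 at 1.997 and ZNF580 at 1.90. The epithelial keratin gene KRT7 and the stress-response gene NUPR1 were both at 1.77 in the authors' deposited table. PLAC4 at 1.65, the monocyte chemokine gene CCL2 at 1.61, the estradiol-forming enzyme gene HSD17B1 at 1.58 and the thymidine phosphorylase gene TYMP at 1.58 completed the 12 largest increases there. ISG15 had the lowest mean signal of the higher list, a log2 CPM of -0.98 against a median of 2.56. NUPR1 (-0.82), NOG (-0.77), ZNF580 (-0.19) and CCL2 (0.07) were also low, so their fold changes are less certain.

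FOSB (NM_001114171), an AP-1 subunit gene, fell by 2.66 on the log2 scale, a 6.32-fold decrease, in the authors' deposited table. HSPA5, which encodes the endoplasmic reticulum chaperone BiP, stood at -2.43, RRAD at -2.34 and EGR1 at -2.27 in the authors' deposited table. FOS had -2.01, JUN -1.87, TCF7 -1.71, UQCC6 -1.69, IQCN -1.63, AZU1 -1.61, RGS1 -1.60 and NR4A2 -1.59 there. Most Pol II changes were small: only 67 higher and 71 lower genes reached 2-fold, and 118 higher and 136 lower genes had a log2 change under 0.5 in size. If libraries of a stage differed by an assumed coefficient of variation of 0.1, 83 higher and 104 lower genes would pass the authors' FDR limit, and at 0.4 none (0) would.

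**Figure D1:**
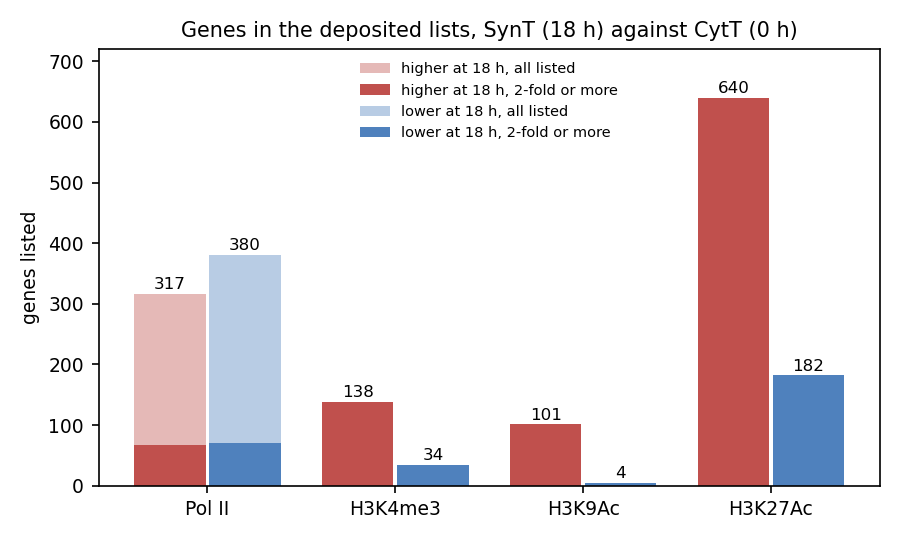
Bars give the number of genes (vertical axis) in the deposited higher (red) and lower (blue) lists of Pol II and 3 histone marks, SynT at 18 h against CytT at 0 h, and the solid part is the genes with a change of 2-fold or more. Pol II had 317 higher and 380 lower genes, of which 67 and 71 reached 2-fold, while H3K27Ac had 640 higher and 182 lower genes.

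Of the 20 fixed gene lists, 5 leaned significantly to one side of the Pol II lists. All 16 listed members of the immediate early and AP-1 list were lower (Fisher's exact test against other listed genes, adjusted p = 0.000609). Besides the genes above they included KLF6 at -1.32, DUSP1 at -1.26 and NR4A3 at -1.11 in the authors' deposited table. Heat shock and unfolded protein response genes were lower in 12 of 13 cases (exact adjusted p = 0.0232), with HSP90B1 at -1.50, CALR at -1.38 and HSPD1 at -1.28 in the authors' deposited table, and TRIB3 as the exception at 0.69. Without genes that have another listed gene within 2 kb, such as CALR beside RAD23A, 9 of 10 members were lower and the exact adjusted p was 0.0619. The log2 odds ratio was -2.46 (95% interval -4.95 to 0.04) against -2.84 (-5.29 to -0.39) with all members, so the call ended with fewer members and a lean of about the same size.

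Trophoblast lists lay on the higher side. Syncytiotrophoblast hormone and surface genes were higher in 7 of 7 cases (exact adjusted p = 0.0142). They were the cytokine gene GDF15 at 1.40, the placental growth factor gene PGF at 1.26, CGA, which encodes the alpha subunit of chorionic gonadotropin, at 1.16, PAPPA at 0.73, INHBA at 0.63, SDC1 at 0.51 and SLC2A1 at 0.45 in the authors' deposited table. Cytotrophoblast and trophoblast stem genes were also higher, in 8 of 8 cases (exact adjusted p = 0.00959). These included KRT7, the transcription factor genes GATA3 at 1.26 and GATA2 at 1.00, KRT18 at 0.79 and EGFR at 0.68 in the authors' deposited table. Keratin and GATA genes are expressed across trophoblast types, so the list's name does not set its members apart from the syncytial ones. Extravillous trophoblast genes were higher in 5 of 5 cases (exact adjusted p = 0.0421), with FN1, the protease inhibitor genes TIMP3 at 1.40 and SERPINE1 at 0.70, and HPGD at 0.39 in the authors' deposited table. The extravillous list had the minimum of 5 members for a test, and its call could not be tested without TIMP3, which lies inside the also listed SYN3 and may share its reads (4 left), or without genes on several lists such as FN1 (3 left). Likewise the cytotrophoblast list had 2 members left without genes on several lists.

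The other lists tested for Pol II missed the threshold. Trophoblast transcription factors were higher in 9 of 11 cases (exact adjusted p = 0.0508), with CEBPB at 1.20 and TBX3 at 1.08 in the authors' deposited table. Interferon response genes were higher in 8 of 10 cases (exact adjusted p = 0.0680), with IFI6 at 1.16, IFIT2 at 1.12 and STAT1 at 0.79 in the authors' deposited table. Matrix and adhesion genes had the same split and adjusted p, with MMP14 at 1.18 and PLAUR at -0.58 in the authors' deposited table. Steroid synthesis genes were higher in 4 of 5 cases (exact adjusted p = 0.223), namely HSD17B1, HSD3B1 at 1.47, CYP11A1 at 0.57 and the aromatase gene CYP19A1 at 0.49, and the LDL receptor gene LDLR was at -0.96 in the authors' deposited table. Cytokine and NF-kB genes were lower in 6 of 8 cases (exact adjusted p = 0.333), with NFKB2 at -1.05 and IL1B at -0.88 in the authors' deposited table. Keratin, junction and actin genes split 4 to 5 (exact adjusted p = 1), with KRT19 at -1.05 and CLDN7 at -0.80 in the authors' deposited table.

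Lists with fewer than 5 Pol II members were not tested. Pregnancy-specific glycoprotein genes were higher in 3 of 3 cases, and hypoxia genes in 4 of 4, with ADM at 1.22, EPAS1 at 0.57 and PKM at 0.44 in the authors' deposited table. The cell cycle list had 1 member, the CDK inhibitor gene CDKN1C, at 1.31 in the authors' deposited table. ERVV-2, a retroviral envelope gene, stood at 1.11 and the E-cadherin gene CDH1 at -0.25 there. ACAT2 at -0.52 and RPL10 at -0.82 were the single cholesterol synthesis and ribosomal protein members in the authors' deposited table. Among histone-modifying enzymes, KDM6B was at -0.65 and SETD1B at 0.46 in the authors' deposited table. Of markers of other cell types, the macrophage receptor gene CSF1R was the single member of the fixed macrophage and blood cell list found for Pol II, at 0.40 in the authors' deposited table, and 0 members of the fixed stromal and endothelial list were found. A longer macrophage list written after the data were seen had 7 of 7 listed members higher, with MAFB at 1.01 and CCR1 at 0.97 in the authors' deposited table.

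**Figure D2:**
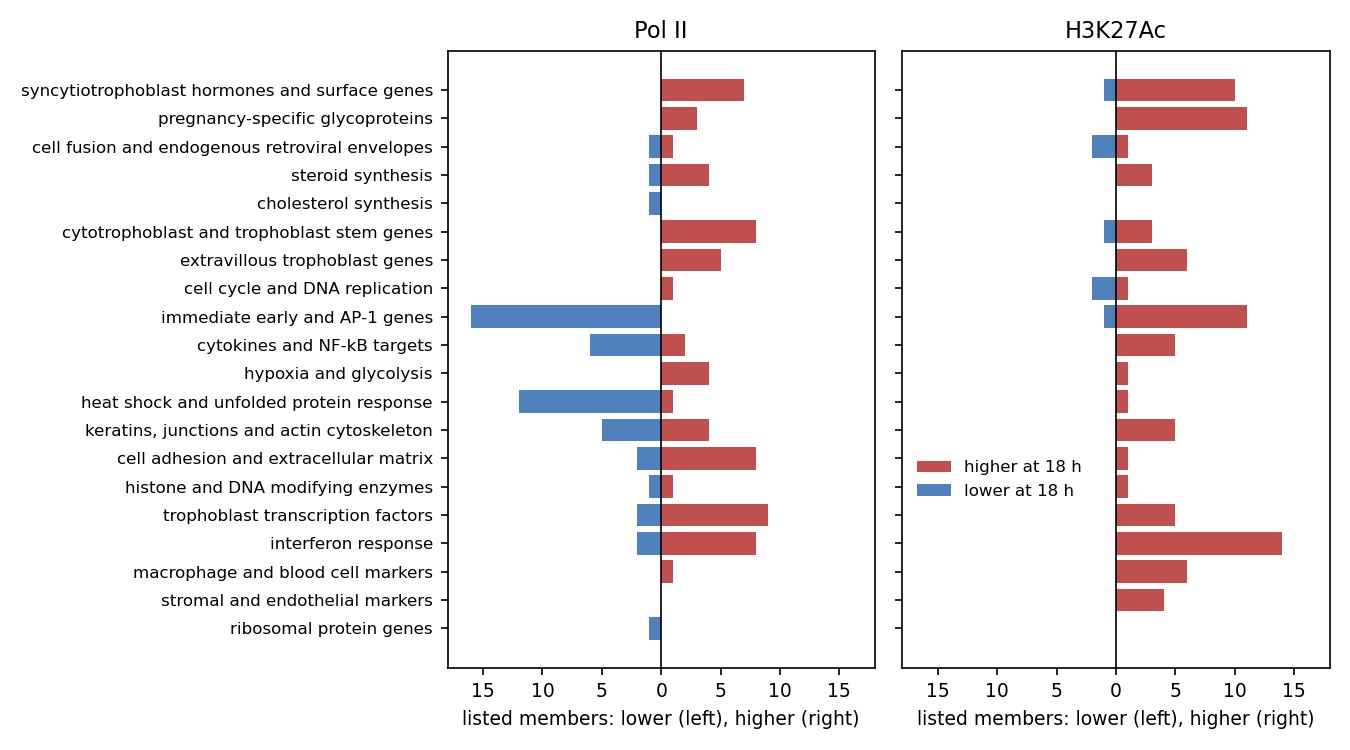
Horizontal bars count the members of each fixed gene list found in the lower (left, blue) and higher (right, red) deposited lists for Pol II and for H3K27Ac. Immediate early genes number 16 lower and 0 higher for Pol II, and 1 lower and 11 higher for H3K27Ac. These are largely different genes: only 4 of the 11 (JUN, JUND, CCN1 and KLF4) are among the 16. Of all listed H3K27Ac genes, 77.9% were higher.

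H3K27Ac, a mark of active promoters and enhancers, was higher over 640 genes and lower over 182, so that 77.9% of listed genes were higher (exact 95% binomial interval 74.9 to 80.7%). That interval treats genes as independent draws and does not measure spread between cultures. NOG (NM_005450) led with a log2 fold change of 3.19, or 9.09-fold, in the authors' deposited table. The estrogen-hydroxylating enzyme gene CYP1B1 followed at 3.14, PSG2 at 3.11, the Notch target gene HES5 at 2.80 and the chemokine genes CCL2 at 2.65 and CCL7 at 2.63 in the authors' deposited table. PSG11 at 2.53, PSG5 at 2.42, ZNF22-AS1 at 2.42, the diamine oxidase gene AOC1 at 2.39, the complement gene C1QA at 2.38 and PSG10P at 2.29 completed the 12 there. On the lower side, the noncoding gene LINC00851 had -5.67 in the authors' deposited table, at the lowest mean signal of that list, a log2 CPM of -2.00. SOX14 stood at -2.68, GCNT4 at -2.42, KRABD1-AS1 at -2.23, CCAT2 at -2.15 and the retroviral envelope gene ERVMER34-1 at -2.14 in the authors' deposited table. SP8 at -2.00, CRNDE at -1.90, ZFAT-AS1 at -1.85, the Wnt receptor ligase gene ZNRF3 at -1.77, CFAP141 at -1.75 and MAFA at -1.71 followed there. Mean signal was also low at CCL7 (log2 CPM -0.42), HES5 (-0.29), SP8 (-0.44), MAFA (-0.22) and KRABD1-AS1 (-0.04). An assumed coefficient of variation of 0.1 would leave at least 585 higher and 144 lower genes past the authors' FDR limit. At 0.4 the count, a lower bound because only listed genes could be ranked, was 0.

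Since most listed genes were higher, a list could hardly exceed the rest in direction, and no fixed list did for H3K27Ac. All 14 listed interferon response genes were higher (Fisher's exact test, adjusted p = 0.436), with ISG15 at 1.98, IFITM1 at 1.87, IFI27 at 1.81 and IFITM3 at 1.71 in the authors' deposited table. All 11 pregnancy-specific glycoprotein genes, including the pseudogene PSG10P, were higher (exact adjusted p = 0.592), from 1.42 for PSG9 to 3.11 for PSG2 in the authors' deposited table. These genes are near-identical copies in a cluster, so values of single members are uncertain. Syncytiotrophoblast genes were higher in 10 of 11 cases (exact adjusted p = 0.592), with GDF15 at 1.86, ALPP, the placental alkaline phosphatase gene, at 1.79, and the relaxin-family hormone gene INSL4 as the exception at -1.04 in the authors' deposited table. The immediate early list was higher in 11 of 12 cases (exact adjusted p = 0.592), with FOSL1 at 1.53 and GADD45B at 1.40 in the authors' deposited table, and NR4A2 at -1.24. Extravillous genes were higher in 6 of 6 cases, and trophoblast transcription factors, cytokine genes and keratin, junction and actin genes in 5 of 5 each, all at the same exact adjusted p of 0.592. Examples in the authors' deposited table are OVOL1 at 1.46, CXCL3 at 1.65, CXCL8 at 1.40 and KRT81 at 1.46.

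Compared instead with all protein-coding genes, many of which may be silent in these cells, 11 of the 20 fixed lists were enriched in the higher H3K27Ac list and 1 in the lower, when every list was tested whatever its number of members. The log2 odds ratio was 9.76 for the pregnancy-specific glycoproteins (exact adjusted p = 2.5e-15), 5.02 for interferon genes (exact adjusted p = 1.2e-13) and 4.22 for immediate early genes (exact adjusted p = 6.9e-09). Macrophage and blood cell markers were among them, with 6 of 6 listed members higher and a log2 odds ratio of 3.32 (exact adjusted p = 0.000686). C1QA, C1QC at 2.17, C1QB at 1.67, S100A9 at 1.58, CSF1R at 1.26 and CORO1A at 1.07 were its members in the authors' deposited table. The stromal and endothelial list, with 4 of 4 listed members higher, had a log2 odds ratio of 2.79 (exact adjusted p = 0.0225), and its members were TAGLN at 2.24, TWIST1 at 2.20, ESAM at 1.41 and PDGFRB at 1.31 in the authors' deposited table. PDGFRB lies within 2 kb of CSF1R, a macrophage list member, so the same reads may count for both lists. TAGLN and ESAM also have a listed neighbour within 2 kb, and TWIST1 had low mean signal (log2 CPM -0.13). The enrichment was not tested without these genes. The smaller lists included the cell cycle genes CDKN1C at 2.18, CCNB1 at -1.23 and MCM6 at -1.02, LY6E at 1.89, ANXA5 at -1.001 and KAT2A at 1.44 in the authors' deposited table.

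H3K4me3, a promoter mark, was higher over 138 genes and lower over 34. The secreted antimicrobial gene RNASE7 (NM_032572) led at 3.10 in the authors' deposited table, followed by the smooth muscle gene TAGLN at 2.47, PSG6 at 2.23, PSG8 at 2.12, OVOL1-AS1 at 2.10 and ERVV-2 at 2.09. SYT8 fell by 2.84, SIGLEC6 by 2.51 and TREX2 by 2.26 in the authors' deposited table, while the purinergic receptor gene P2RY13 had -2.25, the neutrophil Fc receptor gene FCGR3B -2.17 and the formyl peptide receptor gene FPR1 -1.62. TREX2 had the lowest mean signal of the lower list, a log2 CPM of -0.84, and that of FCGR3B was -0.32. By fixed list, 12 of 12 listed interferon genes, 8 of 8 pregnancy-specific glycoprotein genes and 6 of 7 syncytiotrophoblast genes were higher, and none of these 3 lists differed in direction from the other listed genes (Fisher's exact test, adjusted p = 0.381, 0.538 and 1). Since 80.2% of listed genes were higher, a lean to the higher side could hardly be called in lists of this size. IFIT1 stood at 1.68, ALPP at 1.71 and LGALS16 at 1.61, against -1.22 for INSL4 in the authors' deposited table. Stromal and endothelial markers were higher in 3 of 3 cases, too few to test, namely TAGLN, ESAM at 1.74 and CDH5 at 1.56 in the authors' deposited table. Both listed cytotrophoblast genes were lower, BCAM at -1.42 and PAGE4 at -1.32 in the authors' deposited table. An assumed coefficient of variation of 0.1 would leave at least 125 higher and 27 lower genes, whereas at 0.4 no listed gene (0) would pass.

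H3K9Ac, another mark of active promoters, was higher over 101 genes and lower over 4. CYP1B1 (NM_000104) had the largest increase at 2.26, with NOG at 2.22, RNASE7 at 2.01, PSG2 at 2.01, HES2 at 1.96 and the noradrenaline transporter gene SLC6A2 at 1.89 in the authors' deposited table. The 4 lower genes were SOX14 at -1.99, PAGE4 at -1.57, MIMT1 at -1.29 and FOXI3 at -1.02 in the authors' deposited table. Among the fixed lists, 7 of 7 listed interferon genes and 6 of 6 pregnancy-specific glycoprotein genes were higher (Fisher's exact test, adjusted p = 1 for both), with ISG15 at 1.83 and PSG6 at 1.72 in the authors' deposited table. With 96.2% of listed genes higher, the test could not call a higher lean in these lists. Here too 3 of 3 stromal and endothelial markers were higher, too few to test, namely TAGLN at 1.44, TWIST1 at 1.42 and ESAM at 1.33 in the authors' deposited table. With an FDR 10 times smaller, 2 lower genes were left.

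The higher lists of the comparisons shared genes far more often than independent lists would. Genes in the higher lists of Pol II and all 3 marks numbered 14, and 0 genes were in all 4 lower lists. In the order of their Pol II change the 10 first were ISG15, NUPR1, CCL2, TYMP, HSD3B1, HES2, PSG4, IFIT2, PSG2 and ESAM-AS1, and the rest were PSG6, CYP1B1, IFIT3 and CSF2RB. HSD3B1, which makes progesterone from pregnenolone, had 1.47 for Pol II, 1.03 for H3K4me3, 1.24 for H3K9Ac and 1.61 for H3K27Ac in the authors' deposited table. NUPR1 had 1.77, 1.82, 1.71 and 1.64 in the same order there. For Pol II its mean signal was low (log2 CPM -0.82), as was that of ISG15 (-0.98).

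**Figure D3:**
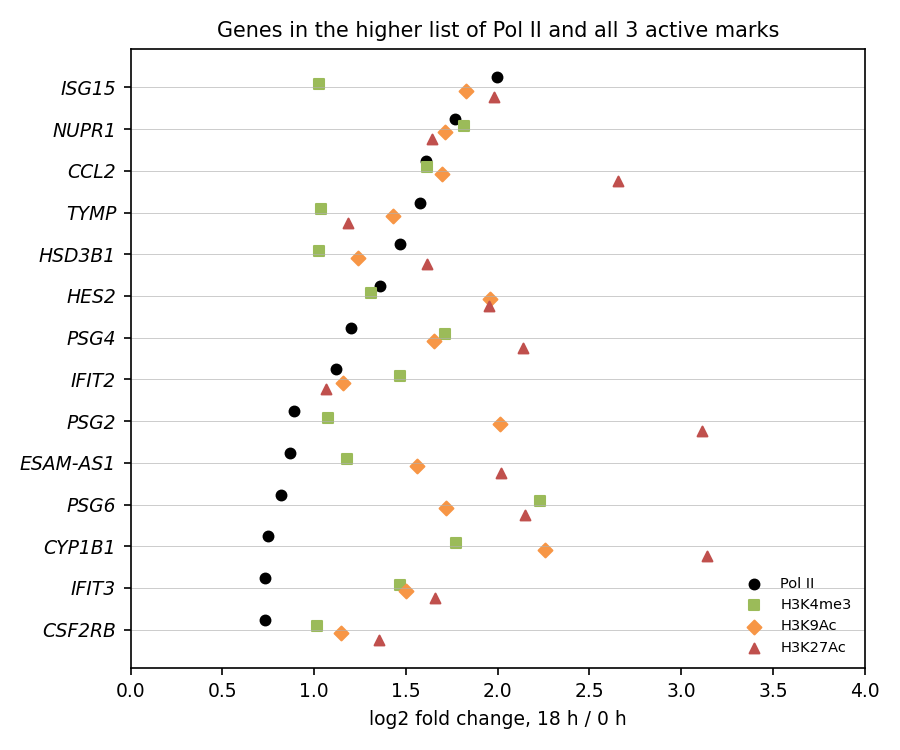
Each row is 1 of the 14 genes in all 4 higher lists, and each symbol its log2 fold change (horizontal axis, 18 h over 0 h) for Pol II or a histone mark, from the authors' deposited table. CYP1B1 ranges from 0.75 for Pol II to 3.14 for H3K27Ac, whereas NUPR1 ranges from 1.64 to 1.82.

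Of protein-coding genes with higher Pol II, 74 were also in the higher H3K27Ac list where 6.87 were expected (Fisher's exact test, adjusted p = 4.7e-55), 34 in that of H3K9Ac (1.09 expected, exact adjusted p = 1.0e-42) and 23 in that of H3K4me3 (1.63 expected, exact adjusted p = 3.5e-20). Between marks, the higher lists shared 70 genes for H3K9Ac and H3K27Ac (1.86 expected, exact adjusted p = 5.2e-106), 67 for H3K4me3 and H3K27Ac (2.78 expected, exact adjusted p = 3.3e-78) and 34 for H3K4me3 and H3K9Ac (0.442 expected, exact adjusted p = 3.8e-57). The ratio of observed to expected depends on the background. With an assumed 10000 genes it was 3.94 in place of 10.8 for Pol II with H3K27Ac. For H3K9Ac with H3K27Ac it was 13.6 in place of 37.6, and all 6 overlaps kept their call. With the 1511 genes of the 8 lists as background, the ratio was below 1 for Pol II with H3K27Ac (0.596) and with H3K4me3 (0.898), since a gene must then be in at least 1 list. For the lower lists of Pol II no overlap passed the threshold: with 22711 genes as background they shared 7 genes with those of H3K27Ac (3.05 expected, exact adjusted p = 0.0509), 1 with those of H3K4me3 (0.569 expected, exact adjusted p = 0.524) and 0 with those of H3K9Ac. Between marks the lower lists shared 5 genes for H3K4me3 and H3K27Ac (0.272 expected, exact adjusted p = 3.9e-05) and 2 each for H3K4me3 and H3K9Ac (exact adjusted p = 3.9e-05) and for H3K9Ac and H3K27Ac (exact adjusted p = 0.00076). If libraries of different antibodies came from the same cultures, which the labels do not state, they would share chance variation, and part of any excess may come from it. This cannot be simulated without library values.

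Genes listed for both Pol II and H3K27Ac numbered 93, of which 93.5% had the same direction (Fisher's exact test, adjusted p = 6.2e-07). The share was 98.8% of 83 genes for H3K4me3 and H3K27Ac (exact adjusted p = 6.2e-07), 100% of 90 for H3K9Ac and H3K27Ac (exact adjusted p = 0.00050) and 97.7% of 43 for H3K4me3 and H3K9Ac (exact adjusted p = 0.0050). Pol II had the same direction as H3K4me3 in 96.4% of 28 genes (exact adjusted p = 0.0857) and as H3K9Ac in 97.4% of 38 (exact adjusted p = 1), where 0 or 1 genes were lower in both. Among genes with fold changes at least 1.5 times the smallest listed, none of the 6 pairs passed the test, with shares of 100% in the 4 pairs that had passed.

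Across genes, which are not independent replicates, larger Pol II changes went with larger H3K27Ac changes (Spearman's rho = 0.51 over 93 genes, permutation adjusted p = 3e-05, Pearson's r = 0.59, permutation adjusted p = 2e-05, from the smallest p the permutations can give, 1e-05). Within the 80 genes higher for both, which include NOG, CCL2 and ISG15, rho was 0.38 (permutation adjusted p = 0.0019), and within the 7 lower for both it was -0.14 (permutation adjusted p = 0.78). Rho was 0.53 for H3K9Ac and H3K27Ac (permutation adjusted p = 3e-05), 0.42 for H3K4me3 and H3K27Ac (permutation adjusted p = 0.00020) and 0.36 for Pol II and H3K9Ac (permutation adjusted p = 0.045). It was 0.24 for Pol II and H3K4me3 (permutation adjusted p = 0.21) and 0.22 for H3K4me3 and H3K9Ac (permutation adjusted p = 0.18). Pearson's r passed the threshold for these last pairs, at 0.62 (permutation adjusted p = 0.0093) and 0.67 (permutation adjusted p = 0.00087), and missed it for Pol II and H3K9Ac, at 0.24 (permutation adjusted p = 0.15). Within genes higher for both, r was only 0.056 for Pol II and H3K4me3 (26 of the 28 genes, permutation adjusted p = 0.79) and 0.14 for H3K4me3 and H3K9Ac (40 of the 43, permutation adjusted p = 0.46), so the few genes that were lower carry these values of r.

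Genes with lower Pol II and a higher mark numbered 8, of which 6 had higher H3K27Ac, 1 higher H3K9Ac and 1 higher H3K4me3. Independent lists among 22711 genes would share 10.7, 1.69 and 2.31 genes, so opposite genes were no more frequent than that. For H3K27Ac the exact adjusted p was 0.479. JUN had -1.87 for Pol II and 1.14 for H3K27Ac in the authors' deposited table, KLF4 -1.22 and 1.03, CCN1 -0.89 and 1.10, and JUND -0.62 and 1.12. PYCARD, which encodes an inflammasome adaptor, had -1.22 and 1.10 and its overlapping antisense gene PYCARD-AS1 -1.20 and 1.53 in the authors' deposited table. Without strand, reads of this pair cannot be told apart. DYNLT4 had -1.16 for Pol II and 1.29 for H3K9Ac in the authors' deposited table. Of the 6 genes with lower Pol II and higher H3K27Ac, 4 were on the immediate early list, against 1 of the 7 genes lower for both (Fisher's exact test, p = 0.103, chosen after the genes were seen).

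**Figure D4:**
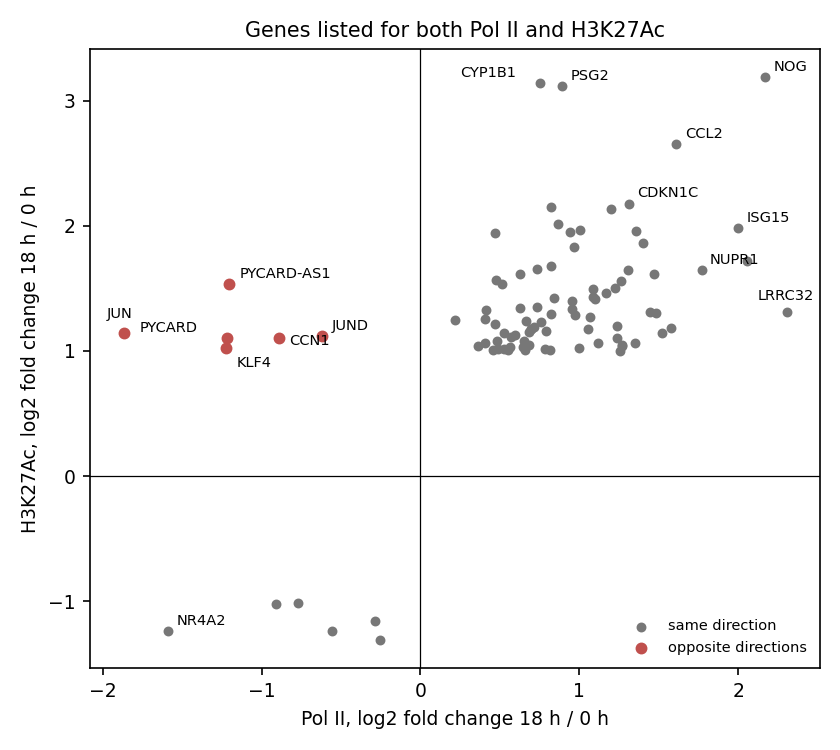
Points are genes listed for both Pol II (horizontal axis) and H3K27Ac (vertical axis), as log2 fold changes of 18 h over 0 h from the authors' deposited table, with opposite directions in red. The red genes, among them JUN at -1.87 and 1.14, sit at the upper left, and no gene lies at the lower right.

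Neighbouring genes can share reads in these tables. Of 69 pairs of Pol II genes lying within 2 kb of each other, 66 had the same direction, as had 50 of 50 pairs for H3K27Ac, 6 of 6 for H3K9Ac and 5 of 5 for H3K4me3. Most listed genes of these marks were higher (77.9%, 96.2% and 80.2%), so many of their pairs would agree anyway. The counts also cannot tell shared reads from real changes in both genes of a pair. GATA3 and GATA3-AS1, with Pol II changes of 1.26 and 1.27 in the authors' deposited table, are a pair within 2 kb. Leaving out such genes ended the call of the heat shock list at a log2 odds ratio of about the same size, left the extravillous Pol II list with too few members to test, and changed no call among the 6 direction comparisons.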

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

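An assumed variation between libraries, a background of 22711 genes, enrichment tests of all 20 lists and leaving out neighbouring genes were chosen after the data were seen, and the other alternatives before. No paired analysis was possible because the tables hold no value per library, so fits with the replicate number as a block, and fits without each replicate in turn, were not run. The tables give no depth.

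Counts moved most. With folds at least 1.5 times the smallest listed, the higher and lower counts were 137 and 148 for Pol II, 36 and 6 for H3K4me3, 14 and 1 for H3K9Ac, and 112 and 20 for H3K27Ac. A 2-fold limit left 67 and 71 Pol II genes. An assumed coefficient of variation of 0.1 left 83 and 104 Pol II genes and 2 lower H3K9Ac genes, and 0.4 left 0 in each of the 8 counts, those of the histone marks being lower bounds. An FDR 10 times smaller left 2 lower H3K9Ac genes. The other 28 recounts stayed within 1.5 times.

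Direction agreement kept its call in 20 of 24 alternatives. With the larger fold limit 4 pairs lost it at 100% agreement, since few or no genes lower in both were left (adjusted p from 0.429 to 1). Overlaps kept direction and call in 28 of 30, but the ratios moved much. With 10000 genes as background the ratio was 3.94 for Pol II with H3K27Ac, against 10.8. With listed genes it was 4.34 for H3K4me3 with H3K9Ac, against 77.0, and 2.06 for H3K9Ac with H3K27Ac, against 37.6. With that background it was below 1 in 2 cases, 0.898 for Pol II with H3K4me3 and 0.596 for Pol II with H3K27Ac. Pearson's r was 0.62 (Pol II, H3K4me3) and 0.67 (H3K4me3, H3K9Ac), now past the threshold, and 0.24 (Pol II, H3K9Ac), now short of it. Within genes higher for both r was 0.056 and 0.14 for the first pairs, so the few lower genes carry these values; for the third the cause was not tested. Within the 7 genes lower for both Pol II and H3K27Ac rho was -0.14.

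Gene lists kept their call in 41 of 58 alternatives that left at least 5 members. Of the Pol II lists with a call, too few were left for syncytiotrophoblast (4), cytotrophoblast (4) and extravillous genes (2) at the larger fold limit, for cytotrophoblast (2) and extravillous genes (3) without shared genes, and for extravillous genes without neighbours (4). Against protein-coding genes, which asks for enrichment in place of direction, 15 lists newly passed. They had entered with at least 5 listed members, which favours enrichment. They were tested on the side to which they leaned, and a negative sign marks enrichment in the lower list. Their log2 odds ratios for Pol II were 4.26 (steroid), -3.69 (cytokine), -3.29 (keratin, where 4 were higher beside 5 lower, with -0.03 in the main test), 4.31 (matrix), 4.30 (transcription factors) and 4.63 (interferon). For H3K27Ac they were 3.87 (syncytiotrophoblast), 9.76 (glycoproteins), 3.56 (extravillous), 4.22 (immediate early), 2.97 (cytokine), 2.87 (keratin), 2.54 (transcription factors), 5.02 (interferon) and 3.32 (blood cells). With no least number of members 10 of 20 lists were enriched in the higher and 4 in the lower Pol II list, and 11 and 1 for H3K27Ac; keratin genes were enriched in both Pol II lists. Interferon genes passed for Pol II at the larger fold limit (3.62), for which the cause was not tested. Heat shock genes did not without neighbours (-2.46 against -2.84), with 10 members in place of 13. Of 414 checks of single gene values under the smaller FDR or a variation of 0.1, 48 fell short.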

Other observations

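The gene groups and tests in this part were chosen after the values were seen, except the fixed list of immediate early genes. Imprinted genes listed for H3K27Ac were 4 higher and 4 lower among 48 (Fisher's exact test against other listed genes, p = 0.0771, unadjusted). CDKN1C, PHLDA2, CD81 and ASCL2, which lie in 1 imprinted region, had 2.18, 1.78, 1.31 and 1.21 in the authors' deposited table. ZIM2 and MIMT1, from the PEG3 region, had -1.15 and -1.37, SGCE -1.05 and ZFAT-AS1 -1.85 in the authors' deposited table. ZIM2 and MIMT1 lie within 2 kb of each other, so the same reads may count for both. Whether each listed member is imprinted in these cells was not tested. Pol II was higher at H19 (1.02) as well as CDKN1C, and lower at KCNQ1OT1 (-0.48), ZNF331 (-0.38) and ZIM2 (-0.28) in the authors' deposited table. H3K4me3 listed 0 of the 48, and H3K9Ac only MIMT1.

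Wnt feedback and target genes were lower in 4 of 5 cases for H3K27Ac (Fisher's exact test, p = 0.00967, unadjusted and on a list written after its genes were seen). SP8 and ZNRF3 had -2.00 and -1.77, the Wnt co-receptor gene LRP5 -1.21 and RNF43 -1.03 in the authors' deposited table, while NOTUM, which encodes a secreted Wnt inhibitor, had 1.95. For Pol II, TCF7 at -1.71 and the beta-catenin gene CTNNB1 at -0.69 were lower and NOTUM at 0.94 was higher in the authors' deposited table. LRP5 and CTNNB1 encode components of the pathway itself, so the list is wider than its name. Mean H3K27Ac signal at SP8 was low (log2 CPM -0.44). TGF-beta and BMP genes were higher in 6 of 6 cases for H3K27Ac (exact p = 0.348), 4 of 4 for Pol II (exact p = 0.0423) and 3 of 3 for H3K9Ac, with ID3 at 1.24 for Pol II and FST at 1.41 for H3K27Ac in the authors' deposited table. Chemokine genes were higher in 9 of 9 cases for H3K27Ac (exact p = 0.219), 5 of 5 for H3K4me3 and 2 of 2 for Pol II, with CX3CL1 at 1.94 (H3K27Ac), CXCL11 at 2.001 (H3K4me3) and CCL8 at 1.31 (Pol II) in the authors' deposited table. CXCL11 had the lowest mean signal of the higher H3K4me3 list, a log2 CPM of -0.84. Of the 29 chemokines, 10 are also on fixed lists, and CCL2 and CCL7 are also on the macrophage list below.

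The p-values imply errors that shrink with the mean signal about as counting error would. The size of counting error itself is unknown, since no depth is given. The part of the implied error that does not shrink with the mean signal was at most 0.744% over the 4 comparisons, as a coefficient of variation. It is not a share of the standard error, whose median for Pol II was 0.092 on the log2 scale. Of 1786 listed genes, counted once in each comparison, 64.4% had an implied standard error under 0.1 on the natural-log scale. That is smaller than 2 libraries per group with a coefficient of variation of 0.1 or more could give. It argues against such a spread having entered the test for those genes. Listing needed an FDR under 0.001, which favours small errors, above all where the change is small, as for Pol II. The share therefore does not describe genes outside the lists. Libraries pooled before the test, a fixed small dispersion and cultures that truly agreed this closely stay open. The genes that depend on this most are small Pol II changes such as TEAD1 (0.17 in the authors' deposited table).

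Immediate early genes had lower Pol II in 16 of 16 listed cases, and 4 of these genes had higher H3K27Ac. Only 12.5% of the 16 had another listed gene within 2 kb (upper exact 95% bound 38.3%), which argues against reads of neighbours as the source. Loss of acetylation does not account for JUN, JUND, CCN1 and KLF4, where the smallest H3K27Ac change was 1.03. These 4 were picked because they were in the higher H3K27Ac list, so their values say nothing of the other members. NR4A2 lost both, and the other 11 genes have no listed H3K27Ac value. Immediate early genes are induced within minutes by handling and dissociation, so the 0 h cells, taken straight after trypsin and Percoll, may carry Pol II loaded during isolation. Whether the 16 genes reflect isolation or differentiation cannot be told apart, since time after isolation and stage change together.

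Neutrophil genes were lower in H3K4me3 in 7 of 9 listed cases (Fisher's exact test against other listed genes, p = 0.000182, unadjusted). This list was written after its genes were seen, so the p-value is no independent support. The 7 were FCGR3B, FPR1, CXCR1 at -1.38, TREM1 at -1.32, MCEMP1 at -1.28, CEACAM3 at -1.17 and CXCR2 at -1.10, against MMP9 at 1.84 and VNN3P at 1.21 in the authors' deposited table. Macrophage genes, of which 1 (MMP9) is also on the neutrophil list, were higher in 100% of 17 listed cases for H3K27Ac (lower exact 95% bound 80.5%), 7 of 7 for Pol II, 6 of 6 for H3K9Ac and 3 of 3 for H3K4me3, with APOE at 1.999, MAFB at 1.96 and TREM2 at 1.82 for H3K27Ac in the authors' deposited table. Fewer leukocytes of every kind at 18 h could lower both sets, and no listed macrophage gene was lower. But the macrophage list was written after the values were seen, and 77.9% of all listed H3K27Ac genes were higher. These counts therefore cannot exclude fewer leukocytes. Fewer neutrophils at 18 h may explain the 7 genes, but the other comparisons list few neutrophil genes and these go both ways: AZU1 at -1.61 and CSF3R at 0.93 for Pol II, S100A9 at 1.58 and MMP9 at 1.57 for H3K27Ac and MMP9 at 1.10 for H3K9Ac in the authors' deposited table, so this cannot be told apart from a change within cells. Of the 39 markers on each list, 3 neutrophil and 12 macrophage ones are also on fixed lists, among them the steroid transporter gene SLCO2B1.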
